A study of Homo sapiens with 12 samples.

How the data were processed

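Gene expression was measured in 12 samples of MDA-MB-231, a human triple-negative breast cancer cell line, on Illumina HumanHT-12 v4 BeadChips. Per the labels, a control subline (Scr) and 2 sublines with knockdown of 14-3-3ζ (ZKD4 and ZKD5) received vehicle or 5 ng/ml TGF-β for 2 h, and each of the 6 groups holds 2 arrays. According to the labels' protocols, total RNA came from a Trizol extraction with RNeasy clean-up and DNase I digestion, passed a Bioanalyser quality control and was turned into biotinylated cRNA with the Ambion MessageAmp kit. Nothing in the labels says that the 2 arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

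The authors deposited 1 gene-level GenomeStudio report for all 12 arrays. Per the file headers it was written by version 1.9.0 of the expression module, with no normalization and no background subtraction. Its AVG_Signal columns hold the mean intensity of the probes of a gene, per the file headers. Its detection p-value columns, per the file headers, rest on 770 negative-control probes. For entries of a single probe they rank the intensity among these, but not for entries averaged over several probes. The deposited report also lists the mean number of beads behind each value, as another column per array. The deposited series matrix held the same intensity values (largest difference 0 over 34593 shared genes), so it could not serve as an independent input. Neither the test used by the authors nor a genome build is given in the sources used here. The control columns carry no subline name and were assigned to Scr because the labels name Scr as the only subline without a knockdown.

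The report covers 34601 gene entries, of which 31331 carry an Entrez ID. Symbols were updated through that ID in an NCBI RefSeq gene table of assembly GRCh38.p14, where 24090 entries matched and 10511 kept the name of the array design. Cytogenetic bands are those listed in the deposited report, for a genome build not given in the sources used here, and no coordinates are given.

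Background was corrected by normexp in limma 3.58.1 (R 4.3.3), with the negative-control level inferred from the detection p-values, an offset of 16, quantile normalization between arrays and log2. The background parameters were fitted on the 27564 entries whose detection p, times 770, was a whole number on all 12 arrays. This was taken as the mark of a single probe, although a bright averaged entry can pass it too. In the other 7037 entries, averaged over several probes, the detection p is not the rank of the averaged signal. Genes with a detection p under 0.01 on at least 2 of the 12 arrays were kept (12871 entries, 8502 of them on all 12 arrays). Where entries shared an Entrez ID (414 did), the brightest was taken, which left 12664 genes. Of 207 genes with several entries, 0 had entries called in opposite directions. The detection filter left out 832 entries, 822 of them averaged over several probes, whose signal reached the array's detection threshold (126.2 to 141.0) on at least 2 arrays.

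Each gene was fitted in limma with 1 mean per group over all 12 arrays, followed by eBayes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, and every adjusted p of a single gene below comes from this fit. The fit had 6 residual degrees of freedom and a prior of 2.73, and the median standard error of a contrast of 2 against 2 arrays was 0.114 on the log2 scale. The contrasts were TGF-β against vehicle in each subline, the difference of that response between each knockdown and Scr and between the average knockdown and Scr, and each knockdown against Scr in vehicle and under TGF-β. The difference of the response between ZKD5 and ZKD4, and ZKD5 against ZKD4 in vehicle, were added later. Values after ± are standard errors of the log2 difference unless named SD. Where a gene was not detected on any array of a group, its level there is only a bound. Its fold is then given as "at least", from the mean of the brighter group over the mean of the higher of each array's lowest detected signal and the gene's own value. No fold is given where both groups were below background or the bound was under 1.

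22 gene lists were written from general knowledge before the data were examined, as were the contrasts, most of the alternative settings and the rule for naming genes. They cover early SMAD targets of TGF-β, bone metastasis genes, hedgehog and GLI genes, immediate early genes, kinase feedback genes, YAP targets, matrix, mesenchymal, epithelial, luminal, interferon, NF-kB, hypoxia, endoplasmic reticulum (ER) stress, cholesterol, heat shock, p53, cell cycle, ribosomal, 14-3-3, fibroblast and blood cell genes. Lists with at least 5 measured members were tested against the other genes with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, and against no change with fry, each adjusted over the lists of a contrast. Members called over all genes are counted beside those called when adjusted over the list alone. Some genes stand in several lists.

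The named genes are, per contrast, the 8 largest rises and 8 largest falls past the threshold whose arrays did not overlap, without unnamed identifiers, and up to 4 called members per list. YWHAZ, PTHLH, GLI2, SMAD7, SKIL, CCN2, IL11, CXCR4, MMP1, ADAMTS1, JAG1, CDKN1A, ID1, PMEPA1 and SFN are named wherever measured. Some genes that the rule takes are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

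The fit was tested on simulated data with 200 changed genes. In the simulated TGF-β contrast of Scr it called 52.2% of the genes changed by 0.5 on the log2 scale, 80.6% of those changed by 1 and 100.0% of those changed by 2. In the simulated difference of responses between ZKD4 and Scr these shares were 14.9%, 44.8% and 89.4%, and for the average knockdown 31.3%, 65.7% and 92.4%. False calls were 12 of 167, 7 of 106 and 13 of 139 calls in these simulations. They were 9 of 154 in a simulated contrast of ZKD4 and Scr in vehicle, each from 1 draw.

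The alternative settings were an offset of 50, no background correction, median scaling, no detection filter, detection on all 12 arrays, the mean of a gene's entries, a trended and robust prior, a fit of only the arrays compared, a replicate block, each array left out in turn, and the 2 other list tests. A filter on the signal and a background fitted on all entries were added after seeing the data. A slide block was not run because the report names no slide. Comparisons that share arrays were set beside 100 simulations of unchanged groups. These held no changed genes, so their shared calls are no chance value for lists of called genes.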

Results

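The data are 12 BeadChip expression profiles of MDA-MB-231 cells, a human breast cancer line used as a model of bone metastasis. A control subline (Scr) was set beside 2 sublines with less 14-3-3ζ, named ZKD4 and ZKD5, each with vehicle or with TGF-β (5 ng/ml, 2 h), with 2 arrays in each of the 6 groups. 14-3-3ζ, the product of YWHAZ, is an adaptor protein that binds phosphorylated partners. The title of the series ties it to the genes that TGF-β switches on in the course of bone metastasis. The arrays were alike in brightness, with median signals of 111.0 to 123.1, and 30.16% to 32.28% of the gene entries were detected on each. Replicate arrays correlated at Pearson's r of 0.9935 to 0.9944 across genes, which are not independent replicates, and the median SD between replicates was 0.117 on the log2 scale. The number of arrays, 2 per group, limits the precision. The first component of the normalized values held 35.0% of the variance and separated ZKD4 from ZKD5, the second (19.1%) separated Scr from both knockdowns and the third (14.5%) separated TGF-β from vehicle.

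YWHAZ (8q22.3a) was the check on the labels and fell in both knockdown sublines. Averaged over vehicle and TGF-β it was lower by a log2 difference of -3.28 ± 0.06 in ZKD4 (limma adjusted p = 2.0e-08) and -3.24 ± 0.06 in ZKD5 (adjusted p = 2.3e-08). The deposited signals were 3395.2 to 4071.0 on the 4 Scr arrays and 402.7 to 581.5 on the 8 knockdown arrays, so no knockdown array came near a control. The log2 differences were -3.27 and -3.46 in vehicle and -3.28 and -3.015 under TGF-β (ZKD4 and ZKD5). In ZKD5, YWHAZ was higher under TGF-β than in vehicle by 0.53 ± 0.08 (adjusted p = 0.011). That call was lost without ZKD5_vehicle replicate 1 (adjusted p = 0.070), ZKD5_vehicle replicate 2 (0.081) or ZKD5_TGFb replicate 2 (0.094), and over all alternatives its adjusted p ranged from 2.3e-04 to 0.19. With a background fitted on all entries the ZKD5 difference was 0.26 (adjusted p = 0.056). Its call was also lost with median scaling (0.19) and with only the arrays compared (0.18). In Scr and ZKD4 the TGF-β difference of YWHAZ was 0.09 (adjusted p = 0.74) and 0.08 (adjusted p = 0.78).

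**Figure D1:**
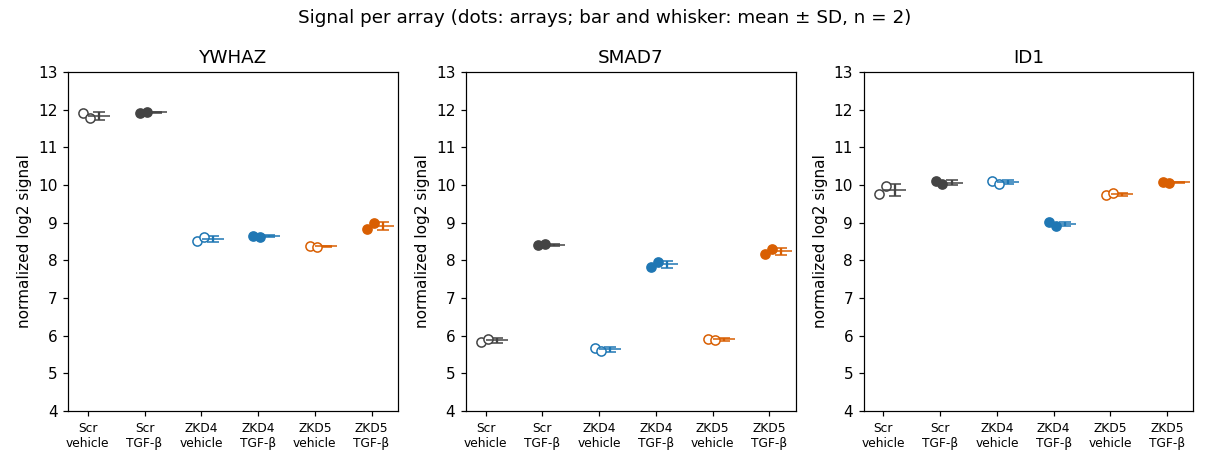
Normalized log2 signal of YWHAZ, SMAD7 and ID1 on each array (dots) with the group mean and SD (n = 2), for vehicle and TGF-β in the 3 sublines. YWHAZ averaged 11.83 and 11.92 in Scr and 8.38 to 8.91 in the knockdowns, SMAD7 rose with TGF-β in all 3 sublines, and ID1 fell to 8.96 in ZKD4 under TGF-β.

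The response of the control subline shows what 2 h of TGF-β does in these cells. In Scr, early SMAD targets of TGF-β were among the genes that rose most. JUNB, an AP-1 subunit, rose by 3.33 ± 0.12 (log2, adjusted p = 1.5e-06, 2 against 2 arrays), BHLHE40, a transcriptional repressor, by 2.79 ± 0.07 (6.5e-07), EDN1, the precursor of endothelin-1, by 2.56 ± 0.09 (1.3e-06) and SMAD7, the inhibitory SMAD, by 2.54 ± 0.08 (1.2e-06). ANGPTL4, a secreted lipase inhibitor, rose by 2.46 and PMEPA1, a membrane protein that restrains TGF-β signalling, by 2.19 ± 0.07 (adjusted p = 1.2e-06). FOSB rose by 2.39. ODAPH and RND1 were not well above background in Scr vehicle, and rose at least 6.32-fold and at least 2.95-fold. SPRY1, an inhibitor of receptor tyrosine kinase signalling, fell by 2.10 ± 0.07 (adjusted p = 1.3e-06), CEBPD fell by 1.33, CITED2 fell by 1.22 and DUSP5, a phosphatase of ERK, fell by 0.87. Smaller rises were seen for SNAI2 (1.51), DLC1 (1.33), DUSP1 (1.28), the urokinase gene PLAU (1.19), IL11 (1.16 ± 0.09, adjusted p = 2.0e-04), CSF2 (1.13), JUN (1.07), CCN2 (1.02 ± 0.10, adjusted p = 5.5e-04), COL4A1 (0.87), PFKFB3 (0.85) and IER3 (0.80). All genes of this paragraph were called in every alternative that measured them. In total 299 genes were called, 211 higher and 88 lower, with a median absolute change of 0.73. The count was 138 to 175 without any 1 of the 4 arrays compared (Scr_vehicle replicates 1 and 2, Scr_TGFb replicates 1 and 2), 183 with median scaling and 90 with only these 4 arrays in the fit.

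In ZKD4 the same leading genes rose. ANGPTL4 rose by 2.67, JUNB by 2.62 ± 0.12 (adjusted p = 1.1e-05), SMAD7 by 2.26 ± 0.08 (2.4e-06), EDN1 by 2.10 and SNAI2 by 1.31. RHOB, a small GTPase, rose by 2.06 and IER3 by 1.23. PMEPA1 and ODAPH, not well above background in ZKD4 vehicle, rose at least 5.51-fold and at least 4.06-fold. SPRY1 fell by 2.42, CITED2 fell by 2.03 and BMP4, a ligand of the TGF-β family, fell by 1.54. PRICKLE1 fell by 1.38, PPP1R3C, a subunit that targets a phosphatase to glycogen, fell by 1.36, DDIT4, an inhibitor of mTOR, fell by 1.19 and ID1, an inhibitor of DNA binding, fell by 1.11 ± 0.09 (adjusted p = 2.2e-04). GADD45A rose by 0.98 and PTGS2, the inducible cyclooxygenase, by 0.94. Altogether 357 genes were called, 232 higher and 125 lower. It was 202 to 233 without ZKD4_vehicle replicate 1, ZKD4_vehicle replicate 2 or ZKD4_TGFb replicate 2, and 89 with only the arrays compared.

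ZKD5 also responded. JUNB rose by 3.05 ± 0.12 (adjusted p = 4.1e-06), BHLHE40 by 2.97 ± 0.07 (3.7e-07), ANGPTL4 by 2.72, EDN1 by 2.53, SMAD7 by 2.34 ± 0.08 (2.2e-06), RHOB by 2.23 and VASN, which encodes a TGF-β binding membrane protein, by 1.89. DUSP1 rose by 1.51, IL11 by 1.40 ± 0.09 (adjusted p = 8.6e-05), PLAU by 1.23 and COL7A1 by 1.11. PMEPA1 and ODAPH, not well above background in ZKD5 vehicle, rose at least 2.27-fold and at least 2.43-fold. SPRY1 fell by 1.98 and CITED2 fell by 1.55. Here 224 genes were called, 160 higher and 64 lower. Without any 1 of the 4 arrays compared (ZKD5_vehicle replicates 1 and 2, ZKD5_TGFb replicates 1 and 2) it was 129 to 146. The count was 347 with a trended and robust prior, 140 with median scaling and 42 with only the arrays compared.

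The 3 responses overlapped. Scr and ZKD4 shared 143 genes called higher and 52 called lower, where independent lists of these sizes would share 3.9 and 0.9, and 1 of the 196 genes called in both went opposite ways. Scr and ZKD5 shared 126 higher and 38 lower (2.7 and 0.4 for independent lists), with 0 of 164 opposite. ZKD4 and ZKD5 shared 116 higher and 38 lower (2.9 and 0.6 for independent lists), with 3 of 157 opposite. In all 3 sublines 141 genes were called the same way, 108 higher and 33 lower. These contrasts share no arrays, but they come from the same fit with a single estimate of the spread per gene. A gene with a small spread is more easily called in each, so the lists are not fully independent. Across genes, the log2 changes correlated at Pearson's r of 0.453 (Spearman's rho 0.220) between Scr and ZKD4, 0.460 (0.215) between Scr and ZKD5 and 0.397 (0.197) between ZKD4 and ZKD5, where genes are not independent replicates.

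**Figure D2:**
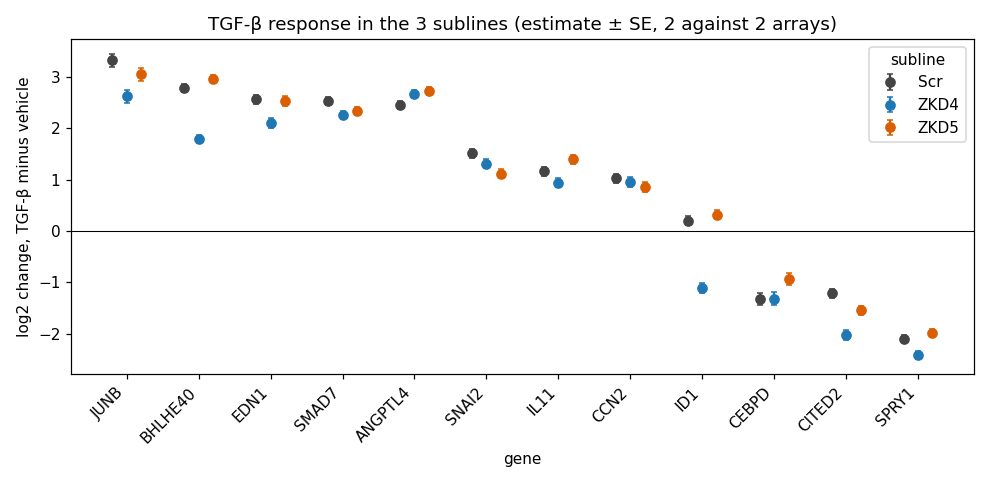
Log2 change with TGF-β (TGF-β minus vehicle) of 12 genes in Scr, ZKD4 and ZKD5, as the limma estimate ± standard error from 2 against 2 arrays. JUNB, EDN1, SMAD7 and ANGPTL4 rose and SPRY1 and CITED2 fell in all 3 sublines, while ID1 fell by 1.11 in ZKD4.

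Among the fixed gene lists, the early SMAD targets moved most. Of 28 measured members, 20 rose and 1 fell in Scr, 16 rose and 3 fell in ZKD4, and 19 rose and 0 fell in ZKD5. When adjusted over the list alone these counts were 20 and 1, 21 and 4, and 21 and 0. The mean change of the list was 1.16, 0.96 and 1.11, and camera's adjusted p with an estimated correlation was 3.9e-04, 0.0011 and 2.5e-04. Matrix genes rose too, with 7 of 24 members higher and 0 lower in Scr, 7 and 0 in ZKD4, and 6 and 0 in ZKD5 (7 and 0, 8 and 1, and 7 and 0 adjusted over the list alone). PLAU and COL4A1 were among them, and the adjusted p with an estimated correlation was 0.016, 0.021 and 0.027. Of 17 YAP targets, 5, 3 and 3 rose and 0 fell (6 rose and 2 fell, 4 and 0, and 9 and 0 adjusted over the list alone), with CCN2 and DLC1 as examples. The adjusted p of the YAP list was 0.11 and 0.087 with an estimated correlation in Scr and ZKD4, and 0.031 in ZKD5. Of 17 immediate early genes, 7 rose and 3 fell in Scr, 7 and 3 in ZKD4 and 6 and 3 in ZKD5 (7 and 5, 8 and 3, and 7 and 7 adjusted over the list alone). JUNB, FOSB and DUSP1 were among those that rose, and the list's adjusted p was 0.11 and 0.087 with an estimated correlation in Scr and ZKD4, and 0.16 by camera in ZKD5. Kinase feedback genes fell more than they rose, with 2 higher and 5 lower of 18 in Scr, 2 and 4 in ZKD4 and 1 and 4 in ZKD5 (3 and 7, 3 and 5, and 1 and 7 adjusted over the list alone). SPRY1 led the falls, and the adjusted p was 0.14, 0.087 and 0.033 with an estimated correlation. With genes detected on all 12 arrays the adjusted p of the kinase feedback list was 0.62 in Scr, 0.79 in ZKD4 and 0.13 in ZKD5, and that of the immediate early list 0.054 in Scr and 0.11 in ZKD4. With a background fitted on all entries the kinase feedback list had 0.062 in Scr and 0.054 in ZKD4. In Scr the kinase feedback call of camera, 0.045, was also lost without any 1 of 9 arrays (0.055 to 0.071), the exceptions being Scr_vehicle replicate 2, ZKD5_TGFb replicate 1 and ZKD5_TGFb replicate 2. In ZKD4 it was lost without ZKD4_TGFb replicate 1 (0.12) or ZKD4_vehicle replicate 2 (0.073), and with no detection filter (0.0502).

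Of 13 mesenchymal genes 2 rose and 0 fell in each subline (2, 4 and 2 rose adjusted over the list alone). SNAI2 was among them. The list's adjusted p was 0.089 by camera in Scr, where the median was -0.02 and the mean 0.24, and 0.087 and 0.033 with an estimated correlation in ZKD4 and ZKD5. In Scr 1 of 10 epithelial genes rose (ELF3, 0.53, adjusted p = 0.048), and in ZKD4 and ZKD5 0 did (2, 0 and 0 adjusted over the list alone). The ELF3 call was lost without any 1 array (0.077 to 0.27) but Scr_vehicle replicate 1 and the pair of ZKD5_TGFb, and with median scaling (0.20), no detection filter (0.098), a trended and robust prior (0.053) or only the arrays compared (0.22). For the epithelial list the adjusted p was 0.14 with an estimated correlation in Scr, 0.97 by camera in ZKD4 and 0.11 with an estimated correlation in ZKD5. The camera calls of the epithelial list were lost with median scaling (0.069 in Scr and 0.094 in ZKD5), in Scr with genes detected on all 12 arrays (0.063) or the mean of a gene's entries (0.069), and in ZKD5 with no background correction (0.067) or no detection filter (0.098). They were also lost in Scr without either ZKD4_vehicle array, either ZKD4_TGFb array, either Scr_TGFb array or Scr_vehicle replicate 1 (0.055 to 0.15), and in ZKD5 without either Scr_TGFb array, either ZKD4_vehicle array, either ZKD5_TGFb array or ZKD5_vehicle replicate 2 (0.051 to 0.18). Of 23 interferon genes 0 rose and 2, 2 and 1 fell (3, 5 and 2 adjusted over the list alone), with an adjusted p of 0.073 by camera, 0.074 with an estimated correlation and 0.096 by camera. Of 20 hypoxia genes 1 rose in each subline and 0, 3 and 0 fell (2 and 2, 1 and 5, and 1 and 1 adjusted over the list alone). The ZKD4 call of camera for hypoxia had an adjusted p of 0.087 with an estimated correlation, 0.077 with no detection filter, 0.14 with the filter on the signal and 0.059 without ZKD4_vehicle replicate 2. The 11 luminal markers had 0 members called by limma in any subline (0 and 1, 0 and 0, and 1 and 0 adjusted over the list alone), and in ZKD5 the list as a whole was higher with a mean of 0.17 (adjusted p = 0.033 with an estimated correlation). Camera did not call the NF-kB list of 23 (3 higher and 4 lower in Scr, 4 and 5 in ZKD4, 2 and 1 in ZKD5), the p53 list of 19 (2 and 1, 2 and 0, 1 and 1), the ER stress list of 24 (1 and 0, 2 and 1, 1 and 2) or the hedgehog and GLI list of 5 (1 and 0, 0 and 0, 0 and 0). These counts adjusted over the list alone were 4 and 7, 7 and 5, and 2 and 4 for NF-kB, 2 and 1, 2 and 2, and 2 and 2 for p53, 2 and 3, 3 and 1, and 2 and 2 for ER stress, and 2 and 0, 0 and 0, and 1 and 0 for hedgehog and GLI. It also left uncalled the 23 cholesterol genes (0 and 0, 0 and 1, 0 and 1), 13 heat shock genes (0 and 0, 1 and 0, 0 and 0), 7 members of the 14-3-3 family (0 and 0, 0 and 0, 1 and 0), 33 ribosomal protein genes and 29 cell cycle genes. The ribosomal and cell cycle lists had 0 members called by limma in any subline, over all genes or adjusted over the list alone. Adjusted over the list alone, cholesterol genes had 0 higher and 1 lower in each subline, heat shock genes 0 and 0, 1 and 0, and 1 and 0, and the 14-3-3 family 0 and 0, 0 and 0, and 1 and 0. Median, mean and direction of the test differed in sign for NF-kB in ZKD4 and ZKD5, p53 in Scr and ZKD4, epithelial genes in ZKD4, luminal and cell cycle genes in Scr, and cholesterol and 14-3-3 genes in ZKD5. Fibroblast markers (3 of 12 measured) and blood cell markers (1 of 12) were too few to test, which leaves contamination by such cells with only single values. TAGLN, a fibroblast marker that MDA-MB-231 cells also express, changed by 0.62, 0.54 and 0.48 with TGF-β in Scr, ZKD4 and ZKD5.

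The genes tied to bone metastasis, the subject of the series, responded in part. Of 19 measured members of that list, 6 rose and 4 fell in Scr, 7 rose and 4 fell in ZKD4, and 5 rose and 0 fell in ZKD5 (7 and 6, 7 and 4, and 7 and 3 adjusted over the list alone). IL11, an osteolytic cytokine, rose by 1.16, 0.94 and 1.40 in Scr, ZKD4 and ZKD5, and CCN2, connective tissue growth factor, by 1.02, 0.96 and 0.85. The ZKD4 call of IL11 was lost with only the arrays compared (adjusted p = 0.053, the highest of a range from 5.5e-07), as were the ZKD4 and ZKD5 calls of CCN2 (0.052 and 0.056). As a whole the list had a camera adjusted p of 0.12 in Scr, and 0.087 and 0.056 with an estimated correlation in ZKD4 and ZKD5. The ZKD4 list call of camera was also lost with no detection filter (0.079) or the filter on the signal (0.060), and without ZKD4_TGFb replicate 1 (0.076) or ZKD4_vehicle replicate 2 (0.059). PTHLH, the gene of parathyroid hormone-related protein, was not well above background in Scr vehicle and rose at least 1.10-fold with TGF-β in Scr (adjusted p = 0.0080). That call was lost without Scr_vehicle replicate 1 (adjusted p = 0.071) or Scr_TGFb replicate 2 (0.070), and its range over the alternatives was 0.0067 to 0.12. It was also lost with only the arrays compared (0.069) and with a background fitted on all entries, where the log2 difference was 0.03 (0.12). In ZKD4, where PTHLH was not well above background in vehicle either, it was not called (adjusted p = 0.49). In ZKD5, where 1 of 2 vehicle arrays detected PTHLH, the difference was 0.37 (adjusted p = 0.20). JAG1, a Notch ligand, changed by 0.71 (adjusted p = 0.016), 0.87 (0.0042) and 0.67 (0.026), of which the ZKD4 value passed in every alternative. The Scr call of JAG1 was lost without Scr_vehicle replicate 1 (adjusted p = 0.12), Scr_TGFb replicate 1 (0.090) or Scr_TGFb replicate 2 (0.11), and the ZKD5 call was lost without any 1 of the arrays of the 3 TGF-β groups or ZKD5_vehicle replicate 2 (0.050 to 0.15). Both JAG1 calls were also lost with median scaling (0.067 and 0.093) and with only the arrays compared (0.11 and 0.21), and the ZKD5 call with no detection filter (0.052). The metalloprotease gene ADAMTS1 fell by 1.02 in ZKD4 (adjusted p = 8.7e-04), with -0.62 in Scr (0.017, and 0.12, 0.090 and 0.097 without Scr_vehicle replicate 1, Scr_vehicle replicate 2 and Scr_TGFb replicate 1) and -0.28 in ZKD5 (0.32). With a background fitted on all entries ADAMTS1 was at -0.15 in Scr (adjusted p = 0.16) and -0.23 in ZKD5 (0.035), and with only the arrays compared the Scr call was lost (0.17). CXCR4, a chemokine receptor, had changes of -0.47 (adjusted p = 0.022), -0.41 (0.036) and -0.03 (0.94), and its calls were lost in 9 of 22 alternatives in Scr, among them without Scr_TGFb replicate 1 (0.11), Scr_TGFb replicate 2 (0.12) or Scr_vehicle replicate 2 (0.17). With a background fitted on all entries CXCR4 was at -0.04 in Scr and -0.02 in ZKD4 (adjusted p = 0.070 and 0.24). In ZKD4 the CXCR4 call was lost in 18 of 22, among them without any 1 array but those of Scr_vehicle (0.060 to 0.22). MMP1, an interstitial collagenase, differed by 0.03, 0.10 and -0.29 (adjusted p = 0.96, 0.87 and 0.55). SFN, another 14-3-3 gene, differed by -0.11, -0.20 and -0.10 (adjusted p = 0.74, 0.40 and 0.79). GLI2 was detected on 0 arrays (signals of 96.7 to 118.7) and SKIL on 1 (106.9 to 144.8), so neither was tested. CDKN1A, the p21 gene, was bright (503.6 to 2568.1) but was left out by the detection p of its averaged probes. In a fit that filtered on the signal, a choice made after seeing the data, CDKN1A rose with TGF-β by 1.81, 1.86 and 1.38 (adjusted p = 9.2e-06, 9.4e-06 and 7.0e-05).

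Whether the knockdown changed the TGF-β response is the question in the title of the series. Averaged over the 28 early SMAD targets the response was 1.16 ± 0.03 in Scr, 0.96 ± 0.03 in ZKD4, which is 83.0% of that in Scr, and 1.11 ± 0.03 in ZKD5, which is 96.0%. The average knockdown differed from Scr by -0.12 ± 0.03, ZKD4 by -0.20 ± 0.04 and ZKD5 by -0.05 ± 0.04. No single gene differed in response between the average knockdown and Scr by limma (0 of 12664 genes, smallest adjusted p 0.306, 862 genes at an unadjusted p under 0.05, and 0 to 16 genes over the alternatives). ID1 differed by -0.60 (adjusted p = 0.31), which passed without background correction (-0.52, 0.035) and with a trended and robust prior (0.043). PTHLH, not well above background in vehicle in Scr and ZKD4, and PMEPA1, not well above background in vehicle in both knockdowns, have no measured difference of responses. SMAD7 differed by -0.24 (adjusted p = 0.70), CXCR4 by 0.25 (0.70), YWHAZ by 0.21 (0.74), MMP1 by -0.13, CCN2 by -0.12, JAG1 by 0.06, SFN by -0.04, ADAMTS1 by -0.03 and IL11 by 0.01 (adjusted p of 0.91 to 0.99 for these last 6). In ZKD5 alone 0 genes were called (889 at an unadjusted p under 0.05), and ID1 differed by 0.12 (adjusted p = 0.91). YWHAZ, SMAD7, CCN2, IL11, CXCR4, MMP1, ADAMTS1, JAG1 and SFN differed by -0.40 to 0.16 in ZKD4 (adjusted p of 0.55 to 0.99) and by -0.33 to 0.44 in ZKD5 (0.58 to 0.995), none of them called. With a background fitted on all entries ADAMTS1 was called, with -0.89 in ZKD4 (adjusted p = 0.0016, from -0.40) and -0.49 in the average knockdown (0.028, from -0.03).

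In ZKD4 alone 6 genes were called, 4 with a higher and 2 with a lower log2 response. ID1 and BHLHE40 had the lower responses, by -1.31 ± 0.13 (adjusted p = 0.015) and -0.997 ± 0.10 (0.017). BHLHE40 still rose by 1.79 in ZKD4, against 2.79 in Scr. TAF15, an RNA-binding protein gene, differed by 1.38 ± 0.12 (adjusted p = 0.011), IPO7, an importin gene, by 1.28 ± 0.12 (0.011), HINT3 by 1.41 ± 0.16 (0.025) and BPNT1, a nucleotidase gene, by 1.22 ± 0.13 (0.017). HINT3 was not detected on all 12 arrays, so that setting gave no value for it. With a background fitted on all entries the differences were 0.99 for TAF15, 0.16 for IPO7, 0.22 for HINT3 and 0.35 for BPNT1, all still called. All 6 calls were lost with only the arrays compared (adjusted p of 0.053 to 0.086), and each was lost without single arrays among the 8 Scr and ZKD4 arrays (0.053 to 0.17). These were all 8 for HINT3, BPNT1 and BHLHE40, 7 for IPO7 (not Scr_vehicle replicate 1) and 6 for TAF15 and ID1 (neither array of Scr_vehicle). The number of called genes without 1 array ranged from 0 to 11, with 10 arrays (all but the pair of ZKD5_vehicle) moving it by over 1.5 times. It was 23 with an offset of 50, 24 with genes detected on all 12 arrays, 36 with a trended and robust prior, 42 without background correction and 44 with a background fitted on all entries. Higher and lower responses were then 14 and 9, 15 and 9, 19 and 17, 20 and 22, and 22 and 22, and with median scaling 5 and 1.

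By list, the early SMAD targets responded less in the average knockdown (median difference -0.17, 0 members called over all genes, and 1 higher and 7 lower adjusted over the list alone). Camera gave this an adjusted p of 2.8e-04, and the adjusted p was 0.15 with an estimated correlation. In ZKD4 the median was -0.25, with 0 higher and 2 lower (2 and 9 adjusted over the list alone) and an adjusted p of 2.0e-05 by camera and 0.074 with an estimated correlation. NF-kB genes had a median difference of 0.16 in the average knockdown (adjusted p = 0.026 by camera, 0.16 with an estimated correlation) and 0.11 in ZKD4 (0.0070 by camera, 0.074 with an estimated correlation). With genes detected on all 12 arrays the NF-kB list had 0.061 in the average knockdown and 0.12 in ZKD4, and with median scaling 0.055 in the average knockdown. The average NF-kB call was also lost without Scr_vehicle replicate 1 (0.062), Scr_vehicle replicate 2 (0.075), Scr_TGFb replicate 1 (0.19) or ZKD5_TGFb replicate 1 (0.051), and the ZKD4 call without Scr_TGFb replicate 1 (0.060). The hypoxia list had a median difference of -0.11 in ZKD4 (adjusted p = 0.0037 by camera, 0.074 with an estimated correlation). In ZKD5 alone 0 of 20 lists were called by camera, with an estimated correlation or by fry. The lower response in the average knockdown therefore cannot be read as shared by both sublines.

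The contrast of ZKD4 and Scr in vehicle shows how the first knockdown subline differed from the control without TGF-β. With 1 subline per knockdown and a single control subline, no contrast of a knockdown with Scr can tell the knockdown from the subline. In ZKD4, cytokine genes were far lower than in Scr. CSF2, encoding GM-CSF, was lower by -2.84 ± 0.09 (adjusted p = 1.5e-06), IL1B by -2.78 ± 0.16 (3.4e-05), CXCL1 by -2.68 ± 0.21 (1.7e-04), CXCL8 (interleukin 8) by -2.16 ± 0.08 (2.3e-06), IL6 by -2.05, and IL11 by -1.12 ± 0.09 (1.8e-04). CCL20 fell below background in ZKD4 and was at least 5.31-fold lower. The acute phase gene SAA1, which has a near-identical copy in SAA2, differed by -2.27, and ZC3H12A, an RNase that degrades cytokine transcripts, by -2.22. Higher in ZKD4 were AKR1C3, a hydroxysteroid dehydrogenase gene not well above background in Scr (at least 3.54-fold), CPED1 (1.91 ± 0.15), ADAMTS1 (1.89 ± 0.11, adjusted p = 3.2e-05), the actin-binding gene TAGLN (1.76 ± 0.06, adjusted p = 2.3e-06), DMKN (1.68) and KRT17 (at least 1.99-fold). Interferon genes were higher, among them OASL (1.43 ± 0.09, adjusted p = 5.9e-05), IFI44 (1.20), IFIT1 (1.06) and OAS2 (at least 1.57-fold). SNAI2 (0.64) was higher too. Matrix genes went both ways, with 7 of 24 higher and 4 lower (7 and 7 adjusted over the list alone), and camera did not call the list (adjusted p = 0.83). Among collagen genes, COL5A1 (0.98) and COL4A1 (0.67) were higher and COL7A1 (-0.74) was lower. Called in all were 1916 genes, 956 higher and 960 lower. Without any 1 of the 4 arrays compared (Scr_vehicle replicates 1 and 2, ZKD4_vehicle replicates 1 and 2) the count was 640 to 812, and it was 1208 without a detection filter, 623 with median scaling and 458 with only the arrays compared.

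By list, 13 of 23 interferon genes were higher and 0 lower in ZKD4 (16 and 0 adjusted over the list alone), with a median of 0.58 and an adjusted p of 8.2e-11 by camera and 0.0032 with an estimated correlation. NF-kB genes went the other way, 0 higher and 16 lower of 23 (1 and 17 adjusted over the list alone), with a median of -0.61 and an adjusted p of 6.7e-14 by camera and 0.0025 with an estimated correlation. Of 24 ER stress genes, 10 were lower and 1 higher (11 and 2 adjusted over the list alone, adjusted p = 0.044 with an estimated correlation). PDIA4 (-1.15), HYOU1 (-1.06), DDIT3 (-0.94) and HSPA5 (-0.89) are chaperone and stress genes among them. Of 29 cell cycle genes 10 were lower and 0 higher (the same counts adjusted over the list alone), such as CDC6 (-0.82) and FOXM1 (-0.78), with an adjusted p of 0.096 with an estimated correlation. The bone metastasis list had 2 higher and 7 lower (3 and 8 adjusted over the list alone, adjusted p = 0.095 with an estimated correlation) and the kinase feedback list 1 and 5 (2 and 8 adjusted over the list alone, 0.076 with an estimated correlation, IER3 at -1.07). The heat shock list had 1 higher and 4 lower by both adjustments (adjusted p = 0.096 with an estimated correlation, 0.21 with median scaling). CXCR4 was lower by -0.44 (adjusted p = 0.011, but 0.077 without Scr_vehicle replicate 2, 0.071 without ZKD4_vehicle replicate 2, 0.077 with median scaling and 0.079 with only the arrays compared), MMP1 differed by -0.44 (0.11) and JAG1 by -0.03 (0.90). CCN2 (0.31), ID1 (0.21), SMAD7 (-0.24), SFN (-0.14) and PMEPA1 (not well above background in ZKD4) had adjusted p-values of 0.063 to 0.36, and PTHLH was not well above background in both groups. CCN2 passed in 5 alternatives (0.010 to 0.038), MMP1 without background correction (0.023) and with a trended and robust prior (0.030), and SMAD7 with genes detected on all 12 arrays (0.047).

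In ZKD5 against Scr in vehicle, LCN2, the siderophore-binding protein lipocalin 2, was lower by -2.76 ± 0.12 (adjusted p = 7.6e-06), the calcium-binding genes S100P by -2.54 and S100A4 by -1.85, AGR2, a disulfide isomerase gene of secretory cells, by -2.06 ± 0.07 (3.8e-06) and PSG4 by -1.93. SCNN1A, HTRA1 and DEFB1 were not well above background in ZKD5 and at least 3.25-fold, 2.99-fold and 2.65-fold lower. Higher in ZKD5 were SERPINB2, a urokinase inhibitor gene (2.15 ± 0.14, adjusted p = 6.0e-05), IL24 (1.74), BATF3 (1.37), RBPMS2 (1.33), ADAMTS1 (1.30 ± 0.11, adjusted p = 2.3e-04) and AADAC (1.24). CXCL8 was higher by 1.02 ± 0.08 (adjusted p = 1.6e-04) and CCN2 by 0.76 (0.0019), while IL1B was lower by -1.81 (3.7e-04) and IL6 by -0.70. The count of called genes was 1350, 512 higher and 838 lower. It was 550 to 736 without any 1 of the 4 arrays compared (Scr_vehicle replicates 1 and 2, ZKD5_vehicle replicates 1 and 2), 866 without a detection filter, 498 with median scaling (119 higher and 379 lower) and 273 with only the arrays compared.

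Interferon genes were lower in ZKD5, with 1 higher and 12 lower of 23 (2 and 15 adjusted over the list alone), a median of -0.46 and an adjusted p of 4.7e-10 by camera and 0.0072 with an estimated correlation. OASL was lower by -1.69 ± 0.09 (adjusted p = 2.8e-05), ISG20 by -1.49, IFIT3 by -1.28 and IFIT2 by -1.22. Of 11 luminal markers 8 were lower and 0 higher (8 and 1 adjusted over the list alone, adjusted p = 0.011 with an estimated correlation), such as AGR2, SPDEF (-1.59) and TFF1 (at least 2.45-fold lower). Of the ER stress genes 9 were lower and 2 higher (14 and 3 adjusted over the list alone, 0.018 with an estimated correlation), with HYOU1 at -0.83 and DNAJB9 at -0.82. Of the hypoxia genes 7 were lower and 1 higher (9 and 1 adjusted over the list alone, 0.030 with an estimated correlation), with NDRG1 at -0.82, PFKFB4 at -0.75 and DDIT4 at -0.72. Of the matrix genes 6 were lower and 2 higher (9 and 2 adjusted over the list alone, 0.038 with an estimated correlation), with the metalloproteinase inhibitor TIMP3 at -1.44 and the collagen crosslinking enzyme LOX at -1.04. Mesenchymal genes (4 lower and 1 higher, and 7 and 1 adjusted over the list alone) had an adjusted p of 0.063 with an estimated correlation, and cholesterol genes (5 lower and 0 higher, 7 and 0 adjusted over the list alone, SCD at -0.81) 0.13 with an estimated correlation and 0.056 without ZKD5_vehicle replicate 1. The NF-kB list (3 higher and 6 lower, 4 and 6 adjusted over the list alone) and the bone metastasis list (4 higher and 7 lower, 4 and 9 adjusted over the list alone, with a mean of 0.01, a median of -0.13 and a lower direction by camera) were not called, with adjusted p of 0.33 and 0.46. CXCR4 was lower by -0.46 (adjusted p = 0.010, and 0.074, 0.056 and 0.050 without Scr_vehicle replicate 2, ZKD5_vehicle replicate 1 and ZKD5_vehicle replicate 2). IL11 differed by -0.51 (0.0089, and 0.066 and 0.060 without Scr_vehicle replicate 1 and ZKD5_vehicle replicate 2) and SFN by -0.46 (0.015, and 0.097, 0.055 and 0.096 without Scr_vehicle replicate 1, Scr_vehicle replicate 2 and ZKD5_vehicle replicate 2). The calls of CXCR4, IL11 and SFN were also lost with median scaling (0.075, 0.061 and 0.115) and with only the arrays compared (0.081, 0.065 and 0.089). The JAG1 call (-0.47, adjusted p = 0.040) was lost in 15 of 23 alternatives, among them without any 1 array but ZKD5_vehicle replicate 1 (0.055 to 0.20). PMEPA1, not well above background in ZKD5, was at least 1.01-fold lower (adjusted p = 0.0039, up to 0.39 over the alternatives, with a background fitted on all entries). MMP1 (-0.45), ID1 (-0.12) and SMAD7 (0.02) had adjusted p-values of 0.11, 0.46 and 0.89, and MMP1 passed without background correction (0.024) and with a trended and robust prior (0.030).

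**Figure D3:**
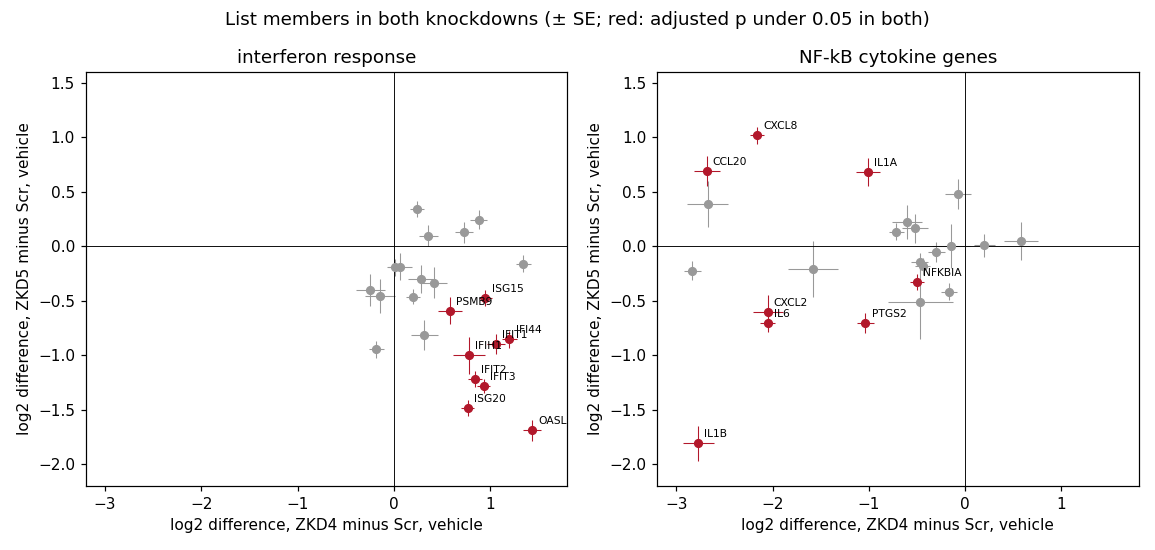
Log2 difference from Scr in vehicle of the measured interferon and NF-kB genes, ZKD4 on the x axis and ZKD5 on the y axis, with standard errors (2 against 2 arrays) and genes called in both knockdowns in red. The 9 interferon genes called in both lie in opposite directions, and among NF-kB genes CXCL8 was at -2.16 in ZKD4 and 1.02 in ZKD5.

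Both knockdowns shared part of their difference from Scr. In vehicle 291 genes were called the same way in both, 132 higher and 159 lower, and 146 of the 437 genes called in both went opposite ways. Independent lists of these sizes would share 38.7 and 63.5, and unchanged groups simulated against the same Scr arrays shared 0.01 genes on average and at most 1 in 100 draws. The simulated groups held no changed genes and so almost no calls to share. Their count is therefore no chance value for the 291 genes. Across genes, which are not independent replicates, the knockdown effects correlated at Pearson's r of 0.221, below the 0.499 of simulated unchanged groups, and their covariance was 0.0210 against a simulated 0.0140. The simulated groups shared the Scr arrays too, so the simulated covariance already holds the spread between those arrays. Scr is a single subline, and a trait of its own would enter both differences with the same sign. Part of the excess may come from it, which splitting the 2 Scr arrays could not have removed. The count of 291 was 85 to 175 without any 1 of the 6 vehicle arrays, 140 without a detection filter, 66 with median scaling (16 higher and 50 lower), 31 with only the arrays compared, and 471 and 470 without background correction and with a trended and robust prior.

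Under TGF-β, CSF2 (-2.75), SAA1 (-2.45), CXCL8 (-2.12), IL6 (-1.95) and IL11 (-1.34, adjusted p = 9.6e-05) were lower in ZKD4 than in Scr. CCL20 and IL1B, not well above background in ZKD4, were at least 4.41-fold and 4.4-fold lower. ID1 was lower by -1.10 (adjusted p = 1.8e-04) and ID2 by -0.85. DDIT4 was lower by -0.47 (adjusted p = 0.0079), against 0.46 in vehicle (0.010), and the difference between these did not pass (0.052). KRT17 (1.82), TAGLN (1.67), ADAMTS1 (1.496) and OASL (1.37) were higher, and AKR1C3, not well above background in Scr, was at least 3.06-fold higher. SMAD7 was lower by -0.52 (adjusted p = 0.0040, and 0.052 with only the arrays compared). CXCR4 was lower by -0.38 (0.016), a call lost in 8 of 22 alternatives, among them without Scr_TGFb replicate 1 (0.068), Scr_TGFb replicate 2 (0.066) or ZKD4_TGFb replicate 2 (0.095), and CXCR4 was at -0.02 (0.11) with a background fitted on all entries. PMEPA1 was higher by 0.25 (0.044), a call lost in 16 of 22, among them without any 1 array (0.0503 to 0.22). CCN2 (0.24), MMP1 (-0.37), JAG1 (0.13) and SFN (-0.23) had adjusted p-values of 0.11 to 0.50. CCN2 passed without background correction (0.036) and with a trended and robust prior (0.033), and MMP1 without background correction (0.042). PTHLH differed by -0.58 (adjusted p = 0.0095, and 0.059 and 0.054 without Scr_TGFb replicate 2 and ZKD4_TGFb replicate 1). The PTHLH call was also lost with only the arrays compared (0.068) and with a background fitted on all entries, where the difference was -0.02 (0.088). Interferon genes (11 higher and 1 lower, 12 and 1 adjusted over the list alone) and NF-kB genes (2 and 14, and 2 and 16 adjusted over the list alone) each had an adjusted p of 0.0071 with an estimated correlation. Early SMAD targets (4 and 13, and 8 and 15 adjusted over the list alone) had an adjusted p of 0.043 by camera and 0.18 with an estimated correlation. The ER stress list (3 and 9, and 5 and 11 adjusted over the list alone) was not called, with an adjusted p of 0.10 by camera and 0.18 with an estimated correlation. Camera called the bone metastasis, cell cycle and kinase feedback lists lower, each with an adjusted p of 0.11 with an estimated correlation. The bone metastasis call was also lost with genes detected on all 12 arrays (0.11), and the kinase feedback call with median scaling (0.055). The SMAD call of camera was also lost with median scaling (0.055) or a background fitted on all entries (0.067), and without Scr_TGFb replicate 1, ZKD4_TGFb replicate 1, either ZKD4_vehicle array or either ZKD5_TGFb array (0.052 to 0.076). 2455 genes were called, 1200 higher and 1255 lower, and 1105 to 1340 without any 1 of the 4 arrays compared (Scr_TGFb replicates 1 and 2, ZKD4_TGFb replicates 1 and 2), with 942 under median scaling (554 higher and 388 lower) and 685 with only the arrays compared.

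In ZKD5 under TGF-β, LCN2 (-2.51), S100P (-2.27), MUC1 (-1.81), S100A4 (-1.77), OASL (-1.66) and AGR2 (-1.60) were lower. The complement gene CFB (-2.07), SPDEF (-1.60), FOSL1 (-1.58), PMEPA1 (-1.03, adjusted p = 1.0e-04) and PTGS2 (-1.03) were lower as well. SERPINB2 (2.07), ADAMTS1 (1.65), AADAC (1.63), IL24 (1.62), BATF3 (1.47) and CXCL8 (1.19) were higher. CCN2 was higher by 0.59 (adjusted p = 0.0053, and 0.051 with only the arrays compared). JAG1 was lower by -0.51 (0.025), a call lost without any 1 of the 4 arrays compared (0.086 to 0.11), and SFN by -0.45 (0.014), a call lost without Scr_TGFb replicate 1 (0.088), ZKD5_TGFb replicate 1 (0.061) or ZKD5_TGFb replicate 2 (0.074). Both were also lost with median scaling (0.10 and 0.11) and with only the arrays compared (0.053 and 0.086), and JAG1 with no detection filter (0.055). IL11 (-0.28), SMAD7 (-0.17), CXCR4 (-0.03) and ID1 (0.002) had adjusted p-values of 0.080 to 0.99. IL11 passed with genes detected on all 12 arrays (0.047), without background correction (0.017) and with a trended and robust prior (0.018), and SMAD7 with a background fitted on all entries (-0.06, 0.042). MMP1 differed by -0.78 (adjusted p = 0.015, and 0.062, 0.075 and 0.086 without Scr_TGFb replicate 1, Scr_TGFb replicate 2 and ZKD5_TGFb replicate 1, and 0.066 with only the arrays compared). PTHLH differed by -0.41 (0.045), a call lost in 18 of 22 alternatives, among them without any 1 array but those of ZKD4_TGFb (0.059 to 0.21) and with a background fitted on all entries, where the difference was -0.02 (0.24). Lower lists were interferon (2 higher and 13 lower, adjusted p = 0.0085), matrix (1 and 8, 0.033), hypoxia (1 and 8, 0.035), luminal (1 and 6, 0.035, but 0.086 by camera with genes detected on all 12 arrays) and ER stress (2 and 9, 0.039), each adjusted p with an estimated correlation unless named. Adjusted over the list alone these counts were 2 and 16, 2 and 10, 1 and 10, 2 and 7, and 5 and 13. Camera also called the mesenchymal, cholesterol, cell cycle and epithelial lists lower. Their adjusted p with an estimated correlation was 0.066, 0.17, 0.22 and 0.15. In total 1729 genes were called, 726 higher and 1003 lower, and 790 to 935 without any 1 of the 4 arrays compared (Scr_TGFb replicates 1 and 2, ZKD5_TGFb replicates 1 and 2), with 1150 without a detection filter, 654 under median scaling and 458 with only the arrays compared (143 higher and 315 lower). Both knockdowns shared 570 genes called the same way under TGF-β, 281 higher and 289 lower (68.8 and 99.4 for independent lists), and 130 of the 700 genes called in both went opposite ways. Both contrasts use the same Scr_TGFb arrays, and unchanged groups simulated against them shared 0.01 genes on average and at most 1 in 100 draws. These simulated groups held no changed genes either, so their count is no chance value for the 570 genes. Across genes the effects correlated at Pearson's r of 0.325, below the simulated 0.499, and their covariance was 0.0340 against a simulated 0.0140. The Scr_TGFb arrays come from the same control subline, so part of this excess may come from traits of that subline.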

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

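All tests of explanations in this part were chosen after the results were seen, and the comparison of the response between ZKD5 and ZKD4 was added then too.

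The TGF-β response of 6 genes differed between ZKD4 and Scr by a test of the difference itself. The difference was -1.309 for ID1, -0.997 for BHLHE40, 1.375 for TAF15, 1.285 for IPO7, 1.412 for HINT3 and 1.215 for BPNT1 on the log2 scale. Without any 1 array each gene kept at least 91.2% of its difference, although leaving out an array also ended the calls. The genes were called for a difference large against the spread between replicates, so the sizes cannot decide on a single deviating array. Background correction may account for much of the size of IPO7, HINT3 and BPNT1, but the share depended on the setting. They kept 12.8%, 15.5% and 28.5% of it with a background fitted on all entries. That fit includes the averaged entries, whose detection p is not the rank of their signal. The same genes kept 78.6%, 80.8% and 88.0% with an offset of 50, and 53.9%, 57.5% and 69.9% with no background correction. All 6 genes passed with each of these 3 alternative settings of background. With median scaling, as another normalization between arrays, each gene kept at least 88.7% of its difference, while wider errors ended the calls of BHLHE40 (-0.885 ± 0.205, from -0.997 ± 0.103), ID1 (-1.232 ± 0.226, from -1.309 ± 0.127) and BPNT1 (1.284 ± 0.217, from 1.215 ± 0.128). Less 2 standard errors, 5 genes kept over 50% and BHLHE40 47.6%, which leaves normalization open for BHLHE40. Handling of the ZKD4 cultures under TGF-β may also account for the 4 genes (TAF15, IPO7 and HINT3 with changes of -0.10, -0.31 and -0.47 in Scr, and ID1 with 0.20) whose change with TGF-β passed in neither Scr nor ZKD5, although ID1 passed in ZKD5 without background correction (limma adjusted p = 0.039) and with a trended and robust prior (0.037), and it cannot be told apart from a response in that subline because both lie in 1 group.

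Against ZKD4, the response in ZKD5 differed for the same 6 genes, by 1.428 for ID1, 1.178 for BHLHE40, -1.641 for TAF15, -1.104 for IPO7, -1.435 for HINT3 and -1.083 for BPNT1. Both comparisons use the 4 ZKD4 arrays, so genes that stood apart there enter both. Unchanged groups simulated with these shared arrays had 0.02 genes called in both on average and at most 1 in 100 draws. The simulated groups held no changed genes and so almost no calls. Their count is no chance value for genes already called in 1 of the comparisons. Between ZKD5 and Scr, without those arrays, the responses of the 6 genes differed by 0.119 for ID1, 0.181 for BHLHE40, -0.266 for TAF15, 0.182 for IPO7, -0.023 for HINT3 and 0.132 for BPNT1 (limma adjusted p of 0.73 to 0.99). The response in ZKD5 also differed from that in ZKD4 for PTGS2 (-1.270), DDIT4 (1.075), PRICKLE1 (0.968) and DUSP1 (0.846). PMEPA1 passed too, but it was not well above background in vehicle in either knockdown, so its -0.952 is no measured difference. In all 18 genes were called between these responses, and the 11 given here are those also named in another comparison of the TGF-β response.

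Gene lists whose response differed by camera were the early SMAD targets, with a median of -0.171 in the average knockdown and -0.247 in ZKD4, the NF-kB genes, with 0.159 and 0.108, and the hypoxia genes, with -0.105 in ZKD4. For the early SMAD targets, loss of at least 50% of the mean TGF-β response in both knockdowns is argued against. Their mean response was lower in the average knockdown by -0.122 ± 0.032, against the -0.580 that such a loss would give. The bound of 50% was set after these means were known, and genes outside the list were not covered. The list contrasts of the response were not called with an estimated correlation. In ZKD5 alone 0 of 20 lists were called by camera or fry.

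Interferon genes differed from Scr in opposite directions in the knockdowns. Background correction and normalization are argued against as the whole cause. The list kept its direction in both knockdowns under 4 settings, with a largest camera adjusted p of 3.008e-08 at the preset correlation. An estimated correlation was not run under these settings, and the p-values do not give the share of the shift that was kept. Loss of YWHAZ acting the same way in both sublines would not by itself give opposite directions. Of the interferon genes called in both knockdowns in vehicle, 9 went opposite ways and 0 the same way. That count restates the flagged pattern and is no separate test of this explanation. A difference between individual sublines apart from the level of YWHAZ stays open: the list's median was lower in ZKD5 than in ZKD4 by -0.712 under TGF-β as well, but with 1 subline per knockdown the subline and its hairpin cannot be told apart. The design could not have singled out the subline as the cause by that test.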

How the results depend on the processing

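The filter on the signal and the background fitted on all entries were chosen after seeing the data. YWHAZ stayed lower in both knockdowns in each alternative that measured it, from -2.93 to -3.86, and detection on all 12 arrays gave no value for it. Of 461 calls of named genes, 342 were kept with median scaling, 274 with only the arrays compared and 398 to 461 in the other settings run on all of them, with 0 reversed, and 385 to 416 without 1 array. The number of arrays and signals near background limit these calls, and the cause was not tested where none is given.

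An offset of 50 gave 23 genes with a differing response in ZKD4 and 2 in ZKD5, and Pearson's r between TGF-β effects of 0.538, 0.550 and 0.478 (Scr with ZKD4, Scr with ZKD5, ZKD4 with ZKD5). No background correction gave 16 genes for the average knockdown, 42 for ZKD4 and 4 for ZKD5, 471 shared knockdown genes, and r of 0.588, 0.603 and 0.525. Median scaling gave 183 TGF-β genes in Scr and 140 in ZKD5, 623 and 498 knockdown genes in vehicle, 942 and 654 under TGF-β, and 66 shared. It moved the share of higher calls from 37.9% to 23.9% for ZKD5 in vehicle, from 45.4% to 24.2% for the shared genes and from 66.7% to 83.3% for the response differing in ZKD4. Its largest shift of the median of all genes was 0.0716. With no detection filter, which tested 33755 genes, the knockdown counts were 1208 and 866 in vehicle and 1150 for ZKD5 under TGF-β, with 140 shared, r of 0.297, 0.287 and 0.254 and Spearman's rho of 0.108, 0.103 and 0.098. Detection on all 12 arrays, with 8379 genes, gave 24 genes for the response in ZKD4, r of 0.567, 0.581 and 0.507 and rho of 0.295, 0.267 and 0.257. A trended and robust prior gave 347 TGF-β genes in ZKD5, 8, 36 and 4 genes with a differing response (average, ZKD4, ZKD5) and 470 shared. Only the arrays compared, a fit with fewer degrees of freedom and no gene list values, gave 90, 89 and 42 TGF-β genes, 0 for the response in ZKD4, 458 and 273 knockdown genes in vehicle, 685 and 458 under TGF-β and 31 shared.

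A background fitted on all entries gave 11, 44 and 13 genes with a differing response and r of 0.668, 0.684 and 0.586. Of 200 list tests, 57 were called by camera, 25 with an estimated correlation and 107 by fry, which does not compare a list with other genes. The bone metastasis list in ZKD5 against Scr under TGF-β turned from lower to higher by limma's fry, with an adjusted p of 0.037 (0.03329 before adjustment), while its mean was 0.07 and its median -0.03.

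Replicate numbers do not pair the arrays: deviations of same-numbered arrays correlated at -0.020 to 0.060 over 15 pairs of groups, with 0 over 0.1. With the replicate block, 270, 324 and 220 genes were called for TGF-β, 9 for the response in ZKD4, 1852 and 1319 for the knockdowns in vehicle, 2410 and 1754 under TGF-β, 292 shared and 56 lists, the early SMAD targets of ZKD4 against Scr under TGF-β being the list not called (0.060). Of the 461 calls of named genes 442 were kept. The 1 call gained was MMP1 in ZKD4 against Scr in vehicle (limma adjusted p = 0.048).

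Without 1 array at a time, where a lone array is assumed to vary like the other groups, the ranges were 138 to 279, 202 to 337 and 129 to 212 TGF-β genes, 0 to 11 for the response in ZKD4, 640 to 1771 and 550 to 1235 knockdown genes in vehicle, 1105 to 2314 and 790 to 1619 under TGF-β, 85 to 259 shared and 49 to 61 lists. YWHAZ ranged from -3.311 to -3.243 and from -3.273 to -3.197. Pearson's r ranged from 0.397 to 0.453, 0.405 to 0.460 and 0.337 to 0.397, Spearman's rho from 0.184 to 0.220, 0.191 to 0.215 and 0.157 to 0.203, and the r between knockdown effects from 0.196 to 0.320.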

Other observations

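All comparisons in this part were chosen after the values were seen, and the genes named here were picked then too.

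Across the knockdowns, 248 genes were called against Scr in both sublines, with and without TGF-β. Of these, 101 were lower in all 4 contrasts and 70 higher. LCN2, lipocalin 2, was lower by -2.02 and -2.76 in vehicle and by -2.17 and -2.51 under TGF-β (ZKD4 and ZKD5). DHRS3, a retinaldehyde reductase gene, was lower by -1.23, -1.41, -1.49 and -1.77, the glycoprotein hormone gene STC1 by -1.37, -1.20, -1.26 and -1.05, and PTGES, a prostaglandin E synthase gene, by -0.84, -1.52, -1.18 and -1.36 (ZKD4 and ZKD5 in vehicle, then under TGF-β). In the same order, RBPMS2 was higher by 1.25, 1.33, 1.20 and 1.17, PHGDH, an enzyme of serine synthesis, by 0.87, 0.67, 0.94 and 0.74, and SERPINE2, a protease inhibitor gene, by 0.62, 0.88, 0.97 and 1.04. The Scr arrays are shared by these contrasts, which can raise such counts, and by how much was not measured.

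Of the 248 genes, 65 were higher in ZKD4 and lower in ZKD5 in both conditions, and 10 were lower in ZKD4 and higher in ZKD5. TAGLN, for example, was at 1.76 in ZKD4 and -1.18 in ZKD5 in vehicle, and PLAAT4, a phospholipase gene, at 1.33 and -1.91. Between ZKD5 and ZKD4 in vehicle 2949 genes were called, 1451 higher and 1498 lower in ZKD5, against 1916 and 1350 for ZKD4 and ZKD5 against Scr.

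With TGF-β, ID2 and ID3, relatives of ID1, changed by -0.82 ± 0.07 (adjusted p = 4.1e-04) and -0.52 ± 0.08 (0.0071) in ZKD4. In Scr their changes were -0.03 and -0.15 (adjusted p = 0.92 and 0.51), and in ZKD5 -0.09 and -0.02 (0.73 and 0.96). The difference of the response between ZKD4 and Scr, -0.78 for ID2 and -0.37 for ID3, did not pass (limma adjusted p = 0.052 and 0.46).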
